A study of Mus musculus with 8 samples.

How the data were processed

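RNA from forepaw skin of 8 C57Bl/6 mice aged 8 weeks was measured on single-colour Affymetrix arrays, 1 array per mouse. Total RNA was copied and biotin-labelled with the WT PLUS kit, which primes along whole transcripts. The mice were 4 Krt16 null animals with paw lesions and 4 wild-type (WT) littermates with normal skin, each genotype with 2 males and 2 females. In the null allele the Krt16 coding sequence is replaced by bacterial LacZ.

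The deposited values are on a log2 scale, 1 value per probe set and array, made by the authors with Partek and RMA (background correction, quantile normalization and probe set summary). The versions, the RMA settings, the genome build and the annotation behind them are not given in the sources used here. The log2 scale was checked on the values, which run from 1.36 to 13.6. RMA compresses large fold changes, and no detection p was used here.

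Of 72688 probe sets, 6732 controls were left out. Of the remaining 65956, the array annotation used here lists 32750, 30604 of them with 1 gene symbol and 2146 with several. Symbols were brought up to date through gene IDs and synonyms in a RefSeq gene table of assembly GRCm38.p6 for 830 probe sets; that table was used only for names and for which genes neighbour each other. This gave 31122 probe sets with exactly 1 gene and 30666 genes, the brightest probe set standing for each of the 360 genes with several. Probe sets shared by several genes were not named, so Krt6a, Krt6b, Sprr2a1, Gclm, Ddx3y and the globin genes, among others, were not analysed here. No filter on dim genes was applied. Medians of the negative control probe sets were 4.26 to 4.46, and the size of a change from a signal under them is not exact. Among the tested genes, 453 share all 8 values with another, and 13 of these were called.

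Arrays have no read depth. The median signal was 4.04 to 4.09 on every array, and the median of the positive control probe sets exceeded that of the negative controls by 3.34 to 3.54 on the log2 scale. The number of arrays limits the precision.

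Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with sex as a covariate and 5 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Effects in each sex and their difference (the interaction) came from a fit of 4 group means with 4 residual degrees of freedom; each group has 2 arrays, so all groups share 1 estimate of the spread. The sex term of the first fit was read as a check of the sex labels. The correlation of the effects in males and females runs across genes, which are not independent replicates, and carries no p.

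For this work 33 gene lists were fixed before the data were examined, covering epidermal programmes, inflammation, cell types the tissue could hold, and sample handling. The 30 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated for each list. Members were also counted after adjustment over the list alone. The mean of each list was compared between genotypes by an exact two-sided permutation test over all 70 assignments, whose smallest possible p is 0.0286. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 prepared the tables, and matplotlib 3.10.9 drew the plots.

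The genes named were set by a rule fixed at the same time. It takes Krt16, all measured members of both epidermal keratin lists, and the 12 largest rises and 12 largest falls among called genes whose null and WT arrays do not overlap. Provisional symbols, microRNAs, small nucleolar RNAs, olfactory and vomeronasal receptors and pseudogenes were passed over. From each list it takes the 2 largest rises and 2 largest falls among called members (3 of each for alarmins, NRF2 targets and stress-induced cornified envelope genes), or the 2 members with the smallest p where none was called. It adds Nfe2l2, Keap1, Esr1, Esr2 and Nnt, the 10 genes with the smallest interaction p, and for sex the label genes and the 5 others with the smallest p. Genes outside the rule are marked where they appear.

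Same-numbered mice of 1 sex were checked for pairing, because the labels number the mice within each sex and genotype. After removal of the group means, the values of same-numbered WT and null arrays correlated at 0.315 in males and 0.114 in females across genes. With 2 mice per group, both pairs of a sex share 1 value. Both lie over the limit of 0.1 set for treating numbers as pairs, so a fit with the 4 pairs as a block was run as an alternative. That mice of 1 number share a litter or a day is not stated in the labels.

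The other alternatives were no sex term, repeated quantile normalization, median centring, filters on dim genes, the mean of a gene's probe sets, all non-control probe sets, no trend, a robust prior, array weights, a 2-fold minimum, each array left out in turn, and fits on 1 sex. Replicate number as a batch term, the mean of the skeletal muscle list as a covariate, the block with estimated list correlations and the block for each sex were added after the data had been seen. With 1 array left out, 1 group keeps a single array, which is assumed to vary like the others.

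The steps were tested on simulated data with 30666 independent genes. For null against WT, with 200 changed genes, 86% were recovered at a log2 change of 0.5, 92% at 1, and 100% at 2 and at 3, with 9 unchanged genes called. For the interaction, 4%, 56%, 96% and 98% were recovered at the same sizes, with 10 unchanged genes called. All 3 lists shifted by 0.5 were recovered and 0 others called; the simulated genes were independent, so this does not test the preset correlation.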

Results

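Gene expression was measured in forepaw skin of 8 mice, 4 lacking keratin 16 and 4 wild-type (WT) littermates, with 2 males and 2 females of each genotype. Krt16 encodes a type I keratin of palm and sole skin and of stressed epidermis. All null samples were labelled as lesions and all WT samples as normal, so genotype and lesion cannot be told apart, and every difference below is one between lesional null and normal WT skin. Values are RMA signals on the log2 scale, given as mean ± SD with n = 4 mice per genotype, and differences are null minus WT with their standard error (SE). Across genes, arrays of the same genotype correlated at r = 0.992 to 0.997 and arrays of different genotype at 0.984 to 0.990. The first principal component held 53.9% of the variance and placed the WT arrays at -26.0 to -20.7 and the null arrays at 19.3 to 31.4.

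The first comparison asks which genes differ between null lesions and WT paw skin. Chitinase-like, calcium-binding alarmin, small proline-rich and protease inhibitor genes rose most. Chil4, a chitinase-like protein, rose from 3.42 ± 0.51 to 10.23 ± 0.59, a difference of 6.81 (SE 0.32, adjusted p = 5.01e-06), and its relative Chil3 by 4.47. S100a8 and S100a9, the subunits of the alarmin calprotectin, rose by 5.69 (SE 0.82, adjusted p = 0.00304) and 5.40 (SE 0.76, adjusted p = 0.00275). The stefin-type cysteine protease inhibitors Stfa1, Csta3 and Cstdc6 rose by 4.76, 4.76 and 4.35, the gasdermin gene Gsdmc2 by 4.44 and the serine protease gene Tmprss11b by 4.29. Each of these genes was higher in all 4 null arrays than in any WT array. WT signals of Chil4 and Csta3, and of Chil3 outside female WT 1, lay under the negative control medians of 4.26 to 4.46. The sizes and the order of rises from such levels are not exact.

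Krt9, the major type I keratin of palm and sole skin, fell most among named genes, from 11.36 ± 0.30 to 8.90 ± 0.73 (difference -2.46, SE 0.26, adjusted p = 0.0007). The other large falls were Krt24, a suprabasal type I keratin (-1.39), the cytochrome P450 genes Cyp4a29 (-1.68) and Cyp2f2 (-1.62), the matrix gene Tnxb (-1.57), the muscle genes Hspb7 (-1.56) and Myoz2 (-1.45), the methyltransferase gene Inmt (-1.45), the neuronal splicing factor gene Nova1 (-1.43), the Wnt antagonist gene Sfrp4 (-1.42), the hedgehog-binding gene Hhip (-1.38) and the granin gene Scg3 (-1.37). Their adjusted p ran from 4.1e-05 for Krt24 to 0.0114 for Tnxb, and all were lower in the 4 null arrays than in any WT array. With the mean of the skeletal muscle list as a covariate, Tnxb (-0.27), Myoz2 (-0.51), Nova1 (-0.45), Sfrp4 (-0.52) and Scg3 (-0.34) were smaller and not called. Inmt (-1.24) and Hhip (-1.51) kept about their size but not their call, as their SE went from 0.15 to 0.29 and from 0.21 to 0.40.

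Over all 30666 genes, 2151 were higher and 1827 lower in null skin. Most changes were small: the median was 0.37 among the higher genes and -0.37 among the lower, while 190 rose and 69 fell at least 2-fold and 34 rose at least 8-fold. Null and WT arrays did not overlap in 5767 genes (18.8%, against 2.86% by chance), 3677 of them called. The higher count dropped to 1302 without male WT 1, 1190 without male null 2 and 1220 without female null 1. The lower count dropped to 1067, 833 and 840 without the same arrays and to 1101 without female null 2. With the mean of the skeletal muscle list as a covariate, which with sex accounts for 73.0% of the genotype term, 236 genes were higher and 106 lower. Of 92 named genes called between genotypes, 62 were not called with this covariate, 19 of them (with the list members Neb and Eno3) at under 0.5 of their reported difference. In the other 43 the median size went from 0.60 to 0.58 and the median SE from 0.0944 to 0.169, and 20 changes were as large or larger, so these losses do not show that muscle accounts for the changes.

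Krt16 itself (gene ID 16666) gave 8.35 ± 1.07 in WT and 6.90 ± 0.07 in null skin, a difference of -1.45 (SE 0.44) that missed the threshold (adjusted p = 0.0617) although all 4 null arrays lay under all WT arrays. The WT values were 8.48 and 8.20 in males and 7.05 and 9.66 in females; the null values lay between 6.83 and 6.99. With same-numbered mice as pairs the adjusted p was 0.0286, and without female WT 1 the difference was -1.98 (adjusted p = 0.000781). Without female WT 2, the highest WT array, Krt16 differed by -0.94 (adjusted p = 0.055), without any other array the adjusted p was 0.112 to 0.150, and with a robust prior it was 0.185. Probe positions were not used here, and probes outside the replaced coding sequence would check nothing about the allele.

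Epidermal keratins moved apart from each other. Of 12 measured members of the basal and suprabasal list, 2 rose and 3 fell, over all genes and also when adjusted over the list alone. Besides Krt9, the suprabasal keratin gene Krt2 fell by 0.60 (SE 0.07, adjusted p = 0.000937) and the basal keratin gene Krt15 by 0.56, while Krt78 and Krt80 rose by 0.44 and 0.45. Differences were 0.20 for Krt14, 0.11 for Krt5, 0.08 for Krt1, -0.08 for Krt10, 0.01 for Krt77, -0.04 for Krt79 and -0.28 for Krt23, none past the threshold. The list as a whole was not called (median -0.02, adjusted p = 0.331). Of the stress keratins only Krt17 and Krt75 were measured, with differences of 0.45 (adjusted p = 0.0995) and 0.33 (adjusted p = 0.38): 0 passed over all genes, 1 had an unadjusted p under 0.05, and 1 was higher when adjusted over the list alone. Their mean was 8.40 ± 0.46 in WT and 8.79 ± 0.09 in null skin. The exact permutation test of that mean gave its smallest possible p of 0.0286 (adjusted p = 0.0629). Krt80 lost its call without male WT 1 (adjusted p = 0.0557), Krt23 gained one without female WT 1 (-0.42, adjusted p = 0.00401) and Krt17 without female WT 2 (0.59, adjusted p = 0.035).

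**Figure D1:**
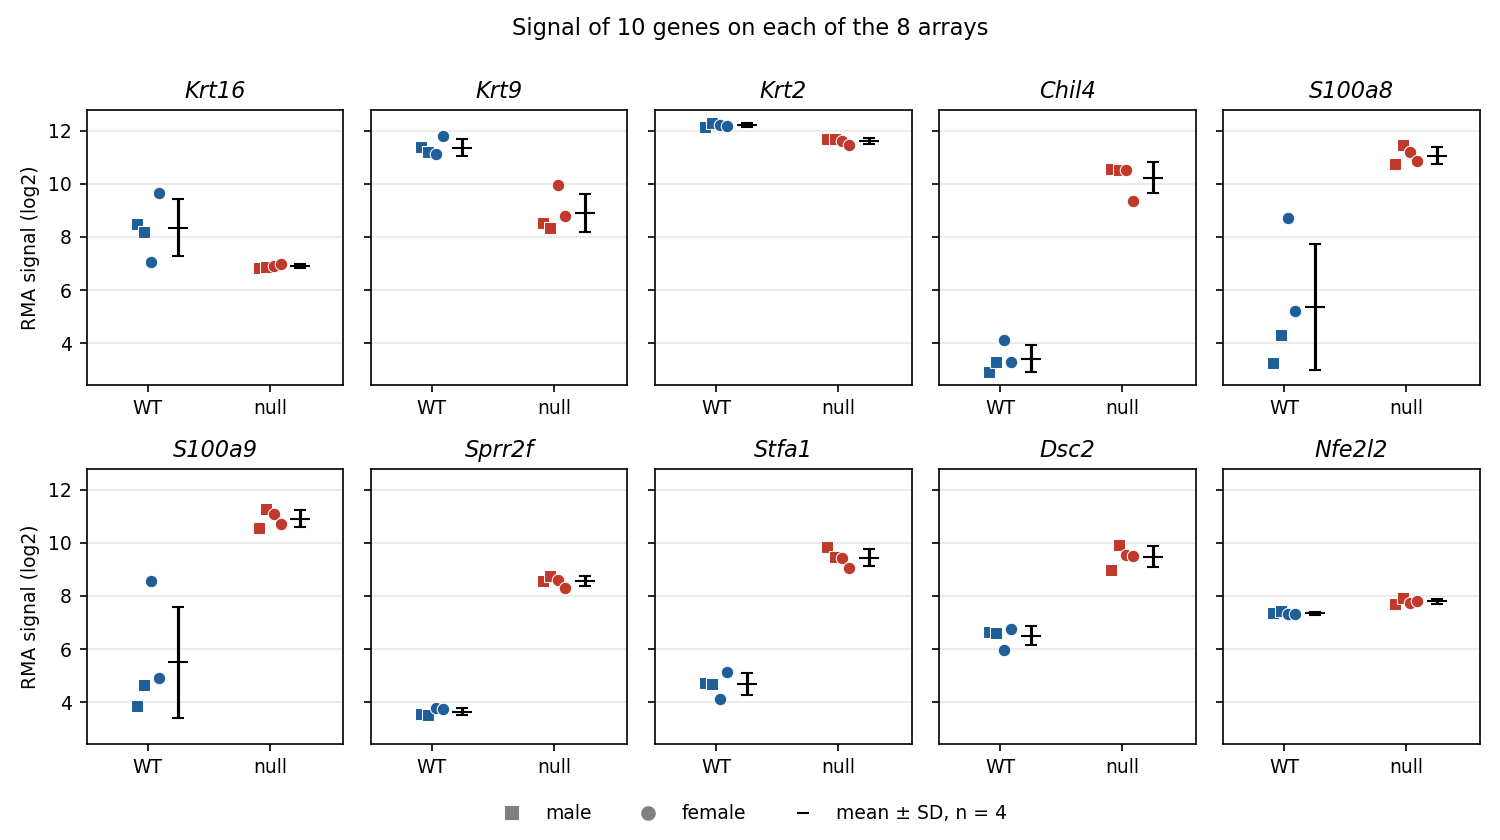
RMA signal (log2) of 10 genes on each of the 8 arrays, WT in blue and Krt16 null in red, males as squares and females as circles, with mean ± SD (n = 4) as bars. Null arrays lay above WT arrays for Chil4 (10.23 against 3.42) and Sprr2f (8.55 against 3.65) and below them for Krt9 (8.90 against 11.36), while female WT 1 stood above the other WT arrays for S100a8 and S100a9.

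Precursors of the stress-induced cornified envelope, the cross-linked protein shell of the outer epidermis, rose together. Of 22 measured members (Sprr, Lce3, Ivl and related genes) 20 rose and 0 fell, the same when adjusted over the list alone, with a median of 3.60. Sprr2f rose from 3.65 ± 0.13 to 8.55 ± 0.19 (4.90, SE 0.11, adjusted p = 5.67e-08), Sprr2d by 4.64 and Sprr2e by 4.38. The WT mean of Sprr2f lay under the negative control medians of 4.26 to 4.46, so the size of its rise is not exact. As a set the 22 members were called (adjusted p = 1.98e-34, and adjusted p = 0.0272 with an estimated correlation). Alarmins and antimicrobial peptides also rose: 18 of 27 over all genes and 20 when adjusted over the list alone, 0 fell, with a median of 1.09 and S100a8, S100a9 and Stfa1 at the top. That list was called too (adjusted p = 1.73e-15; adjusted p = 0.0272 with an estimated correlation). With both the pairs as a block and an estimated correlation, each stood at adjusted p = 0.107. Sprr2, Lce and stefin genes are close paralogs, and signal shared between their probe sets was not excluded.

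The constitutive cornified envelope list, by contrast, held members that moved both ways. Of 32 measured, 6 rose and 10 fell (7 and 14 when adjusted over the list alone). The late envelope genes Lce1m and Lce1l fell by 1.09 and 0.71 (adjusted p = 0.000352 and 0.00304), while the cross-linking transglutaminase genes Tgm5 and Tgm1 rose by 0.73 and 0.60 (adjusted p = 0.00276 and 0.000752). In a count made after the values were seen, 11 of 13 Lce1 genes fell, most of them members of this list. Most of the 10 falls were thus in this 1 family, and the list result below need not hold for the other members. The list was called lower (median -0.18, adjusted p = 0.013; adjusted p = 0.657 with an estimated correlation), and not without female WT 2 (adjusted p = 0.129) or without genes under the median level (0.061).

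Among 25 barrier lipid genes, 10 rose and 2 fell (13 and 4 when adjusted over the list alone). The ceramide desaturase and hydroxylase gene Degs2 rose by 1.39 (adjusted p = 0.000332) and the epidermal lipoxygenase gene Alox12e by 0.94 (adjusted p = 0.0108). The ceramidase gene Acer1 fell by 0.53 (adjusted p = 0.0073) and Sptlc3, of the enzyme that starts sphingolipid synthesis, by 0.38 (adjusted p = 0.0295). Barrier lipid genes as a list were called higher (median 0.19, adjusted p = 0.0204; adjusted p = 0.657 with an estimated correlation). They were not called without male WT 1 (adjusted p = 0.148), male null 1 (0.0538) or female WT 1 (0.073), after repeated quantile normalization (median 0.14, adjusted p = 0.0942) or without genes under the median level (0.0586). Sptlc3 lost its call without male WT 2, male null 2, female WT 2, female null 1 or female null 2 (adjusted p 0.0654 to 0.0989).

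Junction genes split as well. Of 17 desmosome and hemidesmosome genes 2 rose and 4 fell, the same when adjusted over the list alone. The desmosomal cadherin genes Dsc2 and Dsg3 rose by 2.97 (SE 0.21, adjusted p = 7.49e-05) and 1.10 (adjusted p = 0.00117), and the hemidesmosome genes Col17a1 and Dst fell by 0.61 and 0.49 (adjusted p = 0.000299 and 0.00772). The list was not called (adjusted p = 0.715); its median of -0.02 and its test pointed down and its mean of 0.16 up. Of 20 regulators of keratinocyte differentiation 3 rose and 3 fell (4 and 3 when adjusted over the list alone). Hopx, a homeodomain cofactor, rose by 0.61 and the Notch ligand gene Jag1 by 0.50, while the transcription factor genes Maf and Dlx3 both fell by 0.45. That list was not called (median 0.04, adjusted p = 0.744).

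Genes of proliferation and of the wound edge rose. Of 37 cell cycle genes 26 rose and 0 fell (31 and 0 when adjusted over the list alone), each modestly (median 0.37), led by the mitotic motor gene Cenpe (0.79, adjusted p = 0.00327) and the ribonucleotide reductase gene Rrm2 (0.77, adjusted p = 0.00691). Cell cycle genes were called as a list (adjusted p = 6.11e-17; adjusted p = 0.165 with an estimated correlation). Of 22 EGFR ligand and wound-edge genes 14 rose and 1 fell (17 and 1 when adjusted over the list alone, median 0.66). The EGFR ligand gene Epgn rose by 3.11 (SE 0.25, adjusted p = 0.00015) and the prostaglandin synthase gene Ptgs2 by 1.81 (SE 0.52, adjusted p = 0.0494), while Ereg, another EGFR ligand gene, fell by 0.63 (adjusted p = 0.00194). This list was called as well (adjusted p = 8.74e-10; adjusted p = 0.0958 with an estimated correlation). Ptgs2 lost its call without male WT 1, male WT 2, male null 2, female WT 2 or female null 1 (adjusted p 0.0902 to 0.145), and Rrm2 shrank to 0.24 with the muscle covariate, uncalled.

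Targets of NRF2, the transcription factor of the oxidative stress response, changed in both directions. Of 31 measured, 13 rose and 3 fell (16 and 4 when adjusted over the list alone, median 0.21). The glutathione transferase gene Gsta4 rose by 2.13 (SE 0.19, adjusted p = 0.000268), the aldo-keto reductase gene Akr1b8 by 1.65 and the cystine transporter gene Slc7a11 by 1.43, while Aldh3a1, Ephx1 and Gstm1, of detoxification, fell by 0.80, 0.44 and 0.28. NRF2 targets as a list were called higher (adjusted p = 0.000249; adjusted p = 0.319 with an estimated correlation). Nfe2l2, which encodes NRF2, rose by 0.44 (adjusted p = 0.00288, all 4 null arrays above all WT arrays), and its repressor gene Keap1 gave 6.66 in both genotypes (adjusted p = 0.998). The estrogen receptor genes Esr1 and Esr2 differed by -0.27 (adjusted p = 0.0959) and -0.12 (adjusted p = 0.292), and the mitochondrial transhydrogenase gene Nnt by -0.25 (adjusted p = 0.0608). Gstm1 lost its call without male null 2 (adjusted p = 0.0548) or female null 1 (0.0575), Esr1 gained one without male null 1 (adjusted p = 0.019) and Nnt without male WT 2 (adjusted p = 0.0459). With the muscle covariate Slc7a11 shrank to 0.33 and was not called, while Nfe2l2 (0.35), Ephx1 (-0.45) and Gstm1 (-0.25) lost the call with a larger SE (0.12, 0.16 and 0.12 against 0.06, 0.08 and 0.06).

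Cytokine genes rose in part. Of 33 genes of skin inflammation 10 rose and 0 fell (13 and 0 when adjusted over the list alone). Among those named were the IL-20 family genes Il19 (2.67, SE 0.31, adjusted p = 0.00109) and Il24 (1.88, adjusted p = 0.00677). The mean of this list in WT arrays was 3.95, under the negative control medians of 4.26 to 4.46, so sizes and order of rises from such levels are not exact. The list was called higher (median 0.17, adjusted p = 0.00032; adjusted p = 0.372 with an estimated correlation). Of 23 interferon-stimulated genes 0 rose, 3 fell and 20 did not pass (0 rose and 6 fell when adjusted over the list alone); the guanylate-binding protein genes Gbp2 and Gbp3 fell by 0.50 and 0.44. That list was called lower (median -0.13, adjusted p = 0.000185; adjusted p = 0.319 with an estimated correlation), and not without genes under the median level (0.059); without female WT 1 its median was -0.08. Gbp2 lost its call without male WT 1, male null 2, female WT 2, female null 1 or female null 2 (adjusted p 0.0654 to 0.0817), and with the muscle covariate (-0.18).

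Of 12 Langerhans and dendritic cell genes 7 rose and 0 fell (8 and 0 when adjusted over the list alone, median 0.32), with the integrin gene Itgax up by 0.79 and the antigen presentation gene H2-Ab1 by 0.65; the list was called (adjusted p = 9.23e-06; adjusted p = 0.347 with an estimated correlation). Of 13 T cell genes 3 rose and 0 fell (4 and 0 when adjusted over the list alone). Those named were the costimulation gene Icos (1.22, adjusted p = 6.94e-05) and the inhibitory receptor gene Ctla4 (0.59, adjusted p = 0.00507), while the list median was 0.03. Ctla4 went from 3.31 to 3.90, under the negative control medians in both genotypes, and Icos rose from 3.73 in WT arrays, also under them. The T cell list mean was 4.10 in WT arrays, under these medians, and 4.29 in null arrays, within their range. Sizes of rises from such levels are not exact. The T cell list was called (adjusted p = 0.0283; adjusted p = 0.518 with an estimated correlation), and not without female WT 2 (median -0.01, turning its sign, adjusted p = 0.129) or female null 1 (0.0892). Its median was 0.10 without male WT 2, 0.07 without male null 1 and 0.06 without female WT 1. Of 12 neutrophil genes only the chemokine receptor gene Cxcr2 rose (0.44, adjusted p = 0.00837), also when adjusted over the list alone. The neutrophil list was not called (median -0.01, mean 0.09, test upward, adjusted p = 0.506), but was without female WT 1 (median 0.32, adjusted p = 0.000428); without female WT 2 its median was -0.25, uncalled.

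Of 15 macrophage and monocyte genes 1 rose and 3 fell (2 and 6 when adjusted over the list alone, median -0.34). The scavenger receptor gene Cd163 fell by 0.97 and the complement gene C1qc by 0.59, and the integrin gene Itgam rose by 0.71. The list was called lower (adjusted p = 0.0485; adjusted p = 0.657 with an estimated correlation), and not without male null 2 (median -0.15, adjusted p = 0.188), female WT 1 (median -0.21, adjusted p = 0.317), female null 1 (0.089) or female null 2 (0.139), or after repeated quantile normalization (0.114). Of 10 mast cell genes 0 rose and 1 fell (0 and 4 when adjusted over the list alone), the IgE receptor gene Ms4a2 (-0.37, adjusted p = 0.0106). The mast cell list was called lower (median -0.24, adjusted p = 0.0184; adjusted p = 0.372 with an estimated correlation), and not without female WT 1 (adjusted p = 0.0533), female null 2 (0.0781) or genes under the median level (0.0605). C1qc lost its call without any array but male null 1 (adjusted p 0.0551 to 0.108), Itgam without male WT 1, male WT 2, male null 2, female WT 2 or female null 1 (0.0526 to 0.0743) and Cd163 without female null 1 (0.0596). With the muscle covariate Cd163 (-0.35), C1qc (-0.03) and Ms4a2 (-0.18) shrank and were not called.

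Skeletal muscle transcripts were lower in null samples. All 20 measured members had a negative difference, 16 fell over all genes and 20 when adjusted over the list alone, 0 rose, and the median was -0.88. The thin-filament gene Neb fell by 1.05 (SE 0.18, adjusted p = 0.00631) and the muscle enolase gene Eno3 by 1.00 (adjusted p = 0.00876). The list mean was 8.98 ± 0.34 in WT and 8.16 ± 0.22 in null samples. The list was called (adjusted p = 4.52e-14; adjusted p = 0.319 with an estimated correlation). Of 10 smooth muscle genes only the actin-binding gene Synpo2 fell (-0.46, adjusted p = 0.00652), also when adjusted over the list alone, and the list was not called (median 0.10, adjusted p = 0.744). With the muscle list mean as a covariate Neb (-0.22), Eno3 (-0.14) and Synpo2 (-0.17) were not called. Neb and Eno3 are part of that mean, so their shrinking was built in and tests nothing.

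Appendage and fat markers were lower in part. Of 10 sebaceous gland genes 7 fell and 0 rose, the same when adjusted over the list alone, with the melanocortin receptor gene Mc5r at -0.96 and the wax synthesis gene Far2 at -0.73; the list was called (median -0.47, adjusted p = 3.62e-06; adjusted p = 0.165 with an estimated correlation). Of 15 adipocyte genes 0 rose and 4 fell (1 and 5 when adjusted over the list alone), among them the carbonic anhydrase gene Car3 (-0.93) and the lipase gene Pnpla2 (-0.71); the list was called (median -0.22, adjusted p = 0.00105; adjusted p = 0.47 with an estimated correlation). Of 23 hair shaft and root sheath genes 0 passed over all genes or when adjusted over the list alone, and 9 had an unadjusted p under 0.05; S100a3 and Msx2 differed by -0.81 and -0.42. The hair list was called lower (median -0.64, adjusted p = 5.58e-05; adjusted p = 0.535 with an estimated correlation). Its median was -0.40 without male WT 1, -0.38 without male null 2, -0.39 without female WT 2 and -1.03 without female WT 1, called each time. Car3 lost its call without male null 2 (adjusted p = 0.0502) or female null 1 (0.0518), and with the muscle covariate (-0.04). S100a3 (adjusted p = 0.00344) and Msx2 (0.00323) gained one without female WT 1, and S100a3 with the mice paired (0.0465).

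Melanocyte genes rose: 7 of 10 over all genes and 8 when adjusted over the list alone, with 0 and 1 lower. The pigment enzyme genes Tyrp1 and Dct rose by 1.75 (SE 0.22, adjusted p = 0.00159) and 1.36 (adjusted p = 0.00192), and the list was called (median 0.35, adjusted p = 0.00032; adjusted p = 0.372 with an estimated correlation), but not without genes under the median level (0.155). Of 12 endothelial genes 3 rose and 0 fell (6 and 0 when adjusted over the list alone), including the VEGF receptor gene Flt1 (0.40) and the clotting factor gene Vwf (0.27); the list was called (median 0.22, adjusted p = 0.00787; adjusted p = 0.518 with an estimated correlation). Of 16 fibroblast and matrix genes 1 rose and 3 fell, the same when adjusted over the list alone: Postn, of remodelled matrix, rose by 0.97, and the matrix genes Dpt and Dcn fell by 0.86 and 0.83. The fibroblast list was not called (median -0.11, adjusted p = 0.0709), but was with the mice paired (adjusted p = 0.0289), without male WT 2 (median -0.20, adjusted p = 0.0018) or without male null 1 (median -0.20, adjusted p = 0.000677). Its median was -0.07 without male WT 1, -0.05 without male null 2 and -0.02 without female WT 1, uncalled. Dpt lost its call without any array but male null 1 and female WT 2 (adjusted p 0.0612 to 0.101), Dcn without any but male WT 2 and male null 1 (0.0711 to 0.116), Postn without male WT 1 (0.0515) or female null 1 (0.061), and Vwf without male null 2 (0.0564). With the muscle covariate Dpt went from -0.86 to 0.01, turning its sign, Dcn to -0.07 and Postn to 0.32, none of them called.

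Of 11 Schwann cell and myelin genes 1 rose and 3 fell (1 and 4 when adjusted over the list alone): Mal rose by 1.09, and Fa2h and Pmp22 fell by 1.02 and 0.47. Mal and Fa2h are also expressed by other epithelia. The list was not called (median -0.04, adjusted p = 0.0626), but was without male WT 2 (adjusted p = 0.0262). Of 14 sweat gland genes 0 passed over all genes or when adjusted over the list alone, and 1 had an unadjusted p under 0.05; the water channel gene Aqp5 differed by -0.23 and Krt18 by 0.27 (list median 0.04, adjusted p = 0.822). Of 13 cartilage and bone genes 0 passed in either count and 0 had an unadjusted p under 0.05 (median -0.08, adjusted p = 0.475). Chad, a cartilage matrix gene, differed by -1.29 (SE 0.61, adjusted p = 0.217) and the collagen gene Col11a2 by 0.11; Chad passed without male WT 2 (adjusted p = 0.0418) and with the mice paired (0.0115). Of the erythroid list only Alas2 and Slc4a1 were measured, at -0.15 and -0.09, with 0 called in either count and 1 at an unadjusted p under 0.05.

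Lists of sample handling moved as well. Of 14 circadian clock genes 8 fell and 0 rose, the same when adjusted over the list alone, with the clock repressor genes Ciart (-0.87, adjusted p = 0.0113) and Nr1d1 (-0.71, adjusted p = 0.0182); the list was called (median -0.50, adjusted p = 6.73e-07; adjusted p = 0.0704 with an estimated correlation). Of 14 immediate early genes 4 rose and 0 fell (8 and 1 when adjusted over the list alone), with Ier3 up by 0.61 and Jun by 0.44; that list was called (median 0.33, adjusted p = 0.00032; adjusted p = 0.372 with an estimated correlation). Nr1d1 lost its call without male WT 1, male null 2 or female null 1 (adjusted p 0.0563 to 0.0646), and with the muscle covariate (-0.04). Times of day of the harvests are not given in the sources used here.

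Altogether 21 of 30 tested lists were called, 12 higher and 9 lower, and 2 with an estimated correlation, those of the stress-induced cornified envelope and of alarmins. Other groupings of the 8 arrays into 4 and 4 called 2 to 19 lists at the preset correlation, with a median of 13. Groupings with unequal numbers of the genotypes on a side carry part of the genotype difference and called 13 to 19. Those with equal numbers called 2 to 13, so the median of 13 is not a chance level. Only 4 of the 21 lists had their smallest p at the genotype grouping: stress-induced cornified envelope, alarmins, cell cycle, and EGFR ligands with wound-edge genes. Groupings unequal in genotype were among those compared. In the exact permutation test of the list mean, 13 of the 21 called lists, and 1 uncalled list (desmosomes), reached the smallest possible p of 0.0286 (adjusted p = 0.0629). So did the stress keratin list, too short for the camera test. The other 8 called lists did not: p was 0.0571 for interferon-stimulated genes, mast cells, endothelium and adipocytes, 0.114 for immediate early genes, 0.171 for the constitutive envelope, 0.2 for hair and 0.314 for macrophages.

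**Figure D2:**
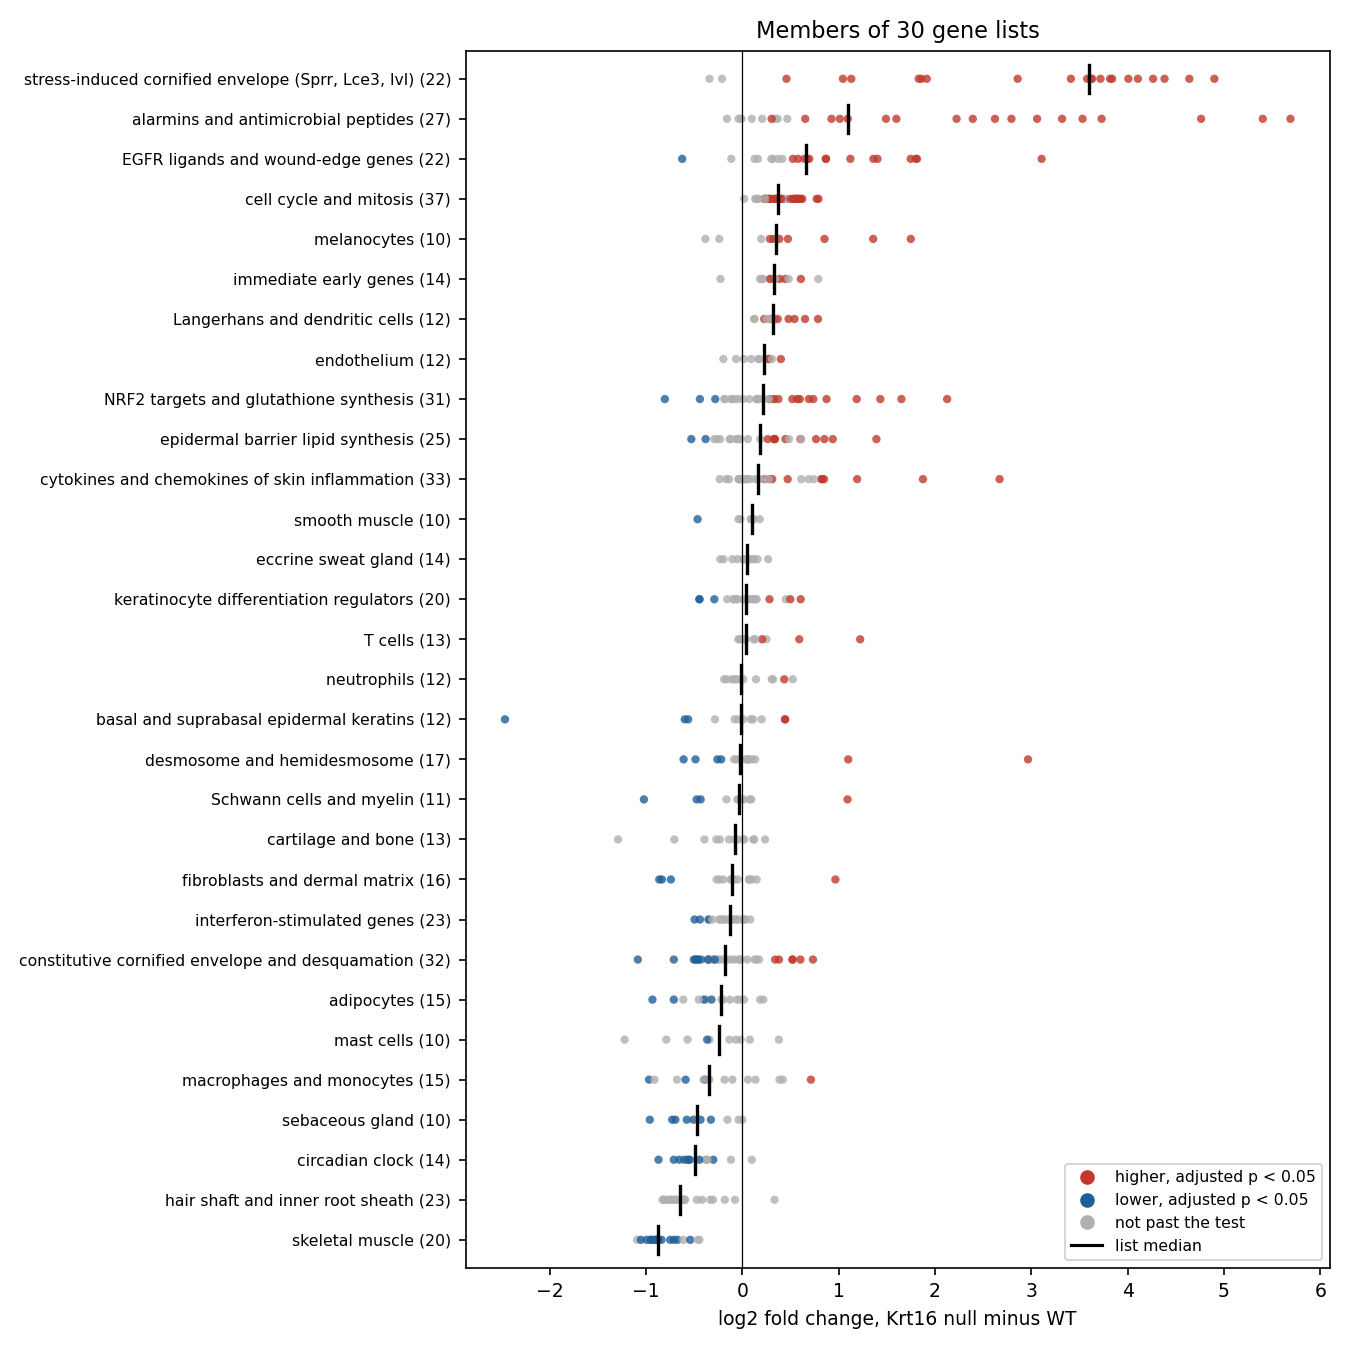
Log2 fold change (null minus WT) of each measured member of the 30 tested lists, 1 point per gene, coloured by whether it passed an adjusted p of 0.05, with the number measured in brackets and a bar at the list median. Medians ran from 3.60 for the stress-induced cornified envelope to -0.88 for skeletal muscle.

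The second comparison asks whether the genotype effect is alike in both sexes. The effects in males and females correlated across all genes at r = 0.787 (Spearman 0.553). In males 489 genes were higher and 188 lower (677), and in females 493 and 426 (919). Of these, 443 were called in both sexes, 442 of them in the same direction. Independent calls would give 10.5, but the calls share 1 estimate of the spread per gene, so this chance figure may be too low. With the mice paired the male count was 1019.

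These counts rest on 2 arrays per group and moved with single arrays. The male count was 133 without male WT 1, 138 without male WT 2, 384 without male null 1, 129 without male null 2, 1331 without female WT 1, 1332 without female WT 2, 425 without female null 1 and 425 without female null 2. The female count was 513 without male WT 1, 521 without male WT 2, 369 without female WT 1, 1469 without female WT 2, 121 without female null 1 and 178 without female null 2. The correlation was 0.733 without male WT 1, 0.685 without male null 2, 0.667 without female WT 2 and 0.741 without female null 1.

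The effect differed between sexes in 2 genes. Defb8, a beta-defensin gene, was 8.52 and 8.46 in male WT, 5.55 and 5.74 in male null, 4.47 and 4.66 in female WT, and 5.33 and 5.18 in female null mice, a difference of effects (female minus male) of 3.54 (SE 0.15, adjusted p = 0.000341). C7, a complement gene, was 6.06 and 6.21 in male WT mice and 3.43 to 3.80 on the other 6 arrays, a difference of effects of 2.35 (SE 0.17, adjusted p = 0.013). In both genes the male WT pair stood apart from the other groups. Over both sexes, C7 differed between genotypes by -1.32 (adjusted p = 0.0605) and passed without female WT 1 (adjusted p = 0.0403) or female WT 2 (0.0441), and S100a7l2 differed by -0.51 and passed without female WT 2 (0.0447). The next 8 genes by p (S100a7l2, Ibsp, Mir7015, Stx19, Atad3aos, Gm12661, Cyp2g1 and Smim18) had an adjusted p of 0.973. At an unadjusted p under 0.05 there were 1297 genes, against 1533 expected by chance. Defb8 kept its call with the mice paired (adjusted p = 0.0117) and without any single array. C7 lost its call with the mice paired (adjusted p = 0.158) and without male WT 1 (0.0824), male WT 2 (0.126), female null 1 (0.14) or female null 2 (0.141), leaving 1 gene called each time, and 28 genes were called without female WT 2.

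Among the lists, 13 were called for the difference between sexes at the preset correlation and 0 with an estimated one, where camera also gave 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.665. Without female WT 1 the number was 8. The hair list had a median effect 0.89 higher in females and the cartilage and bone list one 0.89 lower (-0.89).

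**Figure D3:**
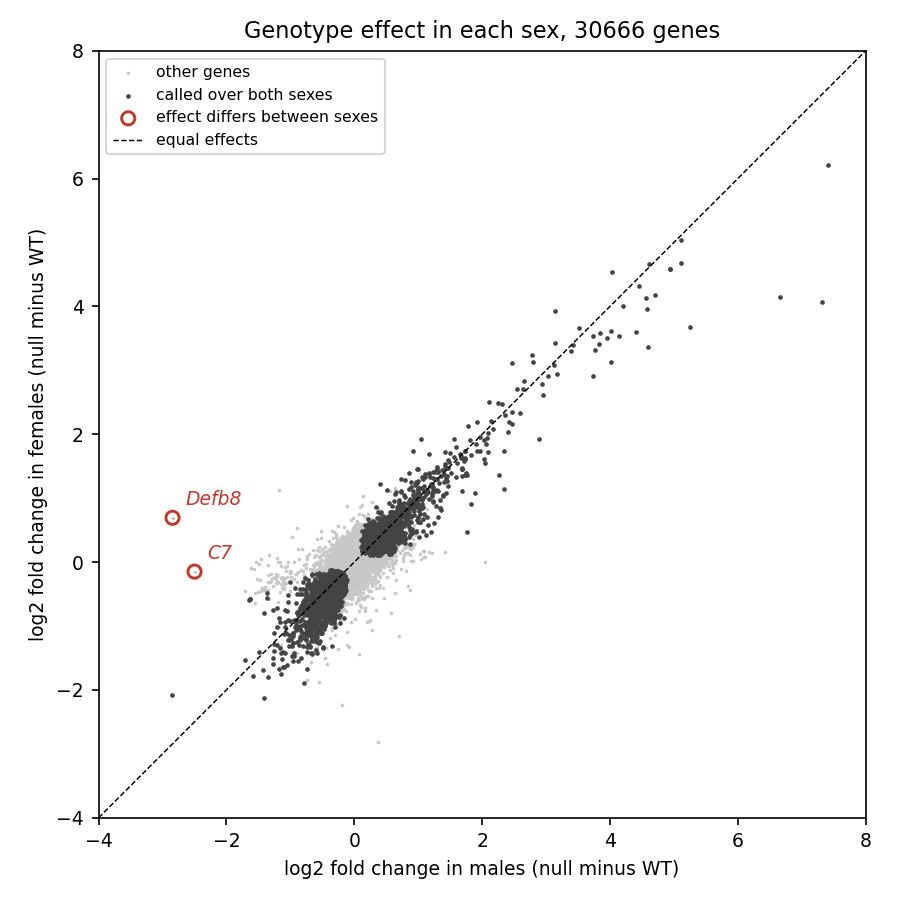
Log2 fold change (null minus WT) of 30666 genes in males (horizontal axis) and females (vertical axis), with the 3978 genes called over both sexes in dark grey, other genes in light grey and the line of equal effects dashed. The circled genes are Defb8 and C7, whose effects differ between sexes by 3.54 and 2.35.

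The sex term served to check the labels. Xist, expressed from the inactive X, and its antisense gene Tsix were higher in females by 6.70 (adjusted p = 1.72e-10) and 1.64 (adjusted p = 2.58e-06). The Y-linked genes Uty, Kdm5d and Eif2s3y were lower in females, with differences of -3.47 (adjusted p = 1.34e-08), -2.44 (adjusted p = 4.95e-08) and -3.48 (adjusted p = 2.47e-07). These 5 genes were the only ones called, with 1527 at an unadjusted p under 0.05. Kdm6a, which escapes X inactivation, differed by 0.58 (adjusted p = 0.0633), Gm22960 by 0.76 (0.168), Gm18852 by 0.63 (0.227) and Npy1r by 0.41 (0.262). By genotype, 0 of the 4 measured label genes passed, over all genes or when adjusted over the list alone, and 1 had an unadjusted p under 0.05; Xist differed by -0.21 and passed without male WT 2 (-0.27, adjusted p = 0.0415), and Eif2s3y differed by 0.20. Kdm6a differed by -0.20 between genotypes (adjusted p = 0.094), passing without female WT 1 (0.0339) and with the mice paired (0.0399).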

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

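Whether chance could give the counts was tested by a plan made in advance; the tests on female WT 1, on neutrophils and on muscle were chosen only after the results were seen. Of 34 groupings of the 8 arrays into 4 and 4 that could be fitted, the genotype grouping called 3978 genes and the highest other 1. Thus 1 of 34 reached that count. Many of these groupings do not hold 2 males and 2 females on each side as the real one does. Those that do are too few for a share under 0.05. Chance is therefore not excluded by this share, although no other grouping came near 3978. For sex, the real grouping called 5 genes and the highest other 2, and 1 of 34 reached that count. Groupings that balance the genotypes as the sexes do are again too few, so chance is not excluded by this share. If same-numbered mice are pairs, the sexes differ between pairs, which leaves still fewer groupings. The 5 genes called for sex were Xist, its antisense gene Tsix and the Y-linked Uty, Kdm5d and Eif2s3y. That all 5 are such genes argues against chance for them, apart from the share. For the lists, the real grouping called 21 and the highest other 19 (male WT 1, male WT 2, male null 1 and female WT 1 against the rest). That other grouping is unequal in genotype, so it carries part of the genotype difference. Groupings with equal numbers of each genotype on a side called 2 to 13 lists. Although 1 of 34 reached the real total of 21, groupings with 2 males and 2 females on each side are too few. Chance is therefore not excluded for that total by this share. The genotype grouping itself called 19 lists without either female WT or either female null array. It called 19 after repeated quantile normalization and 15 without genes under the median level. If same-numbered mice are pairs, only 8 groupings part all 4 pairs, too few for a share under 0.05; there the highest other called 0 genes and 15 lists. Those 15 lists came from groupings unequal in genotype. Single list calls stay open, since an estimated correlation left 2.

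A first pattern is female WT 1, low in Krt16 (7.05) and high in S100a8 and S100a9. Of 328 groups of 4 arrays tested, 34 had a distant array, where chance (about 1 in 20, for any array) gives 16.4. Female WT 1 was the distant array in 11 of these 34, though not for Krt16, S100a8 or S100a9. The groups are not independent, since genes vary together and list means hold some of the same genes. A lesional or mislabelled null sample is argued against by the 20 called stress-induced cornified envelope genes. They lay at a median position of -0.0528 (quartiles -0.0934 and 0.0134) between the other WT arrays at 0 and the null arrays at 1. Their calls came from a fit that counts this array as WT. Over all 22 measured members, called or not, the mean was 6.01 in female WT 1. It was 6.08 to 6.31 on the other WT arrays and 8.89 to 9.11 on the null arrays. S100a8, S100a9 and Chil3 in that array lay above the other WT arrays, toward the null arrays. RNA of neutrophils or their precursors may account for S100a8 and S100a9 there, since 11 of 12 neutrophil markers were highest in that array among the WT arrays. For Krt16, less hair or nail tissue stays open and cannot be told apart from other causes: its hair list mean minus that of the other WT arrays was -1.28, but a null array reached a mean of 6.86. The labels give no difference between this mouse and the other WT female, so no biological difference named by the design could be set against these.

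A second pattern is the rise of S100a8 and S100a9 in all null arrays, by 6.80 and 6.43 over the WT arrays other than female WT 1. More neutrophils as the main source cannot be told apart from other sources: the 12 markers were higher by a median of 0.349 (quartiles 0.123 and 0.567), but 8 of them lay at or under the negative controls in those WT arrays, so a small rise excludes nothing. Cxcr2 and Csf3r, expressed by mature neutrophils, were higher by 0.51 and 0.72 in null arrays and by 0.32 and 0.79 in female WT 1, where S100a8 and S100a9 were higher by 4.44 and 4.10. The granule genes Ngp and Ltf, expressed by precursors, were higher by 1.23 and 0.81 in null arrays and by 3.69 and 2.66 in female WT 1, with a median over all markers of 0.859 there. Expression by keratinocytes of the lesion may also account for the rise, a hypothesis that bulk tissue cannot test.

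The last pattern is the lower skeletal muscle signal in null samples. Thicker epidermis diluting all deeper tissue alike, with no other change there, is argued against. Over 38 fibroblast, endothelial and smooth muscle genes the median difference was 0.0777 (quartiles -0.113 and 0.161). The skeletal muscle genes had a median of -0.88 and a highest value of -0.45. Medians were -0.11 for fibroblasts, 0.22 for endothelium and 0.10 for smooth muscle. Outside this test, the adipocyte (-0.22) and mast cell (-0.24) lists were lower. Changes of their own in these lists could mask dilution, so a partial one is not excluded. Uneven amounts of muscle taken with the skin may account for the lower muscle signal and cannot be told apart from a difference in the paws themselves. The muscle list mean ranged over 0.766 among WT arrays and 0.514 among null arrays, close to the difference of -0.82 between genotypes. Genotype and lesion, which the labels confound, stay open as well.

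Other single arrays lay far from the rest of their group, the nearest other value following each. Akr1b8 was 5.99 in male WT 2 (6.18), Csta3 3.28 in male WT 2 (3.55), Ereg 8.74 in male WT 1 (9.03), Esr2 3.98 in male WT 1 (4.16) and Lce1l 9.81 in male WT 1 (10.09). Inmt was 6.66 in male WT 1 (6.10) and 4.33 in female null 1 (4.89). In male null 1, C7 was 3.80 (3.47), Mal 7.24 (7.79) and Slc7a11 7.44 (7.95), and in male null 2 Krt1 was 12.21 (12.30). Ier3 was 7.28 in female WT 2 (7.42), Jun 7.05 (7.22) and Slc4a1 4.75 (4.98). In female null 2, Chil4 was 9.35 (10.51), Gsdmc2 7.74 (8.36), Krt17 9.32 (9.59) and Alas2 4.78 (4.68), and in female null 1 Ibsp was 6.59 (6.24).

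In female WT 1, C1qc was 6.46 (6.11), Chil3 5.47 (3.31), Dpt 9.56 (8.96), Itgam 6.43 (5.62), Myoz2 8.34 (7.21), Krt17 8.46 (9.27), Krt23 6.44 (6.92) and Krt75 6.94 (7.91). Its list means were 7.70 for stress keratins (8.62), 5.45 for neutrophils (4.18) and 6.29 for macrophages and monocytes (5.84). List means also stood apart for cell cycle in male null 2 (6.95; 6.79), T cells in female null 1 (4.37; 4.28), adipocytes in male null 2 (5.26; 5.52) and Schwann cells in male WT 1 (6.37; 6.25).

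The genotype effect differed between sexes in Defb8 (3.54) and C7 (2.35; not called with the mice paired, adjusted p = 0.158), and in 13 lists at the preset correlation, all of them lost with an estimated one (smallest adjusted p 0.665). The female minus male medians were -0.20 for stress-induced cornified envelope, -0.16 for EGFR ligands and wound-edge genes, -0.12 for interferon-stimulated genes, -0.20 for macrophages, -0.27 for fibroblasts, -0.15 for endothelium, -0.44 for skeletal muscle, -0.14 for smooth muscle, -0.15 for adipocytes, 0.29 for sebaceous gland, 0.89 for hair, -0.89 for cartilage and bone, and -0.23 for immediate early genes.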

How the results depend on the processing

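Replicate number as a batch term, muscle as a covariate, the block with estimated list correlations and the block for single sexes were chosen after the data had been seen. Except for the settings given here, each count stayed within 1.5 times its reported value, and under no setting was a gene called in the opposite direction to its reported call. A 2-fold minimum, which by construction removes genes, left 190 higher and 69 lower, 187 in males and 234 in females. The muscle covariate left 236 higher and 106 lower; among the called genes the median size of change went from 0.37 to 0.30 and the median SE from 0.0722 to 0.126, and 3876 of 3978 kept their sign. Leaving out 1 array gave 1190 to 2271 higher, 833 to 1855 lower, 129 to 1332 in males, 121 to 1469 in females, 1 to 28 for the interaction, 5 to 7 for sex, correlations of 0.667 to 0.791, 19 to 23 lists by genotype and 8 to 16 for the interaction. Array weights gave 1177 in males and fits on 1 sex 1165 in males and 371 in females. Genes at or above the median level gave 1 for the interaction, 3 for sex and a correlation of 0.850, and all non-control probe sets gave 8 for sex.

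Krt16 passed without a sex term (-1.45, adjusted p = 0.0444), with pairs as a block (-1.45, adjusted p = 0.0286), with array weights (-1.42, adjusted p = 0.0212), with replicate number (-1.45, adjusted p = 0.0457) and with the muscle covariate (-3.06, adjusted p = 0.0482); without single arrays it ran from -1.98 to -0.94. The block gave 1019 genes in males and 1 for the interaction. It added genotype calls for Chad, Kdm6a, S100a3 and the fibroblast list, ended the interaction call of C7 (adjusted p = 0.158) and changed no other reported call. An estimated correlation left 2 lists by genotype and 0 for the interaction, and with the block as well 0 (6 at an unadjusted p under 0.05). Over 130 named genes, 2628 of 2837 comparisons stayed on the same side of the threshold (46 of them uncalled genes whose sign changed), 177 lost the call and 31 gained one. Of the losses, 61 came from the muscle covariate, where also the Dpt log2 fold change went from -0.86, called, to 0.00638, uncalled. Besides the 19 that shrank to under 0.5 of their size, that covariate ended the calls of 43 genes, of which 20 changed as much or more than reported while the median SE went from 0.0944 to 0.169: Acer1, Alox12e, Cenpe, Ciart, Ctla4, Cxcr2, Dct, Degs2, Dlx3, Dsg3, Dst, Ephx1, Flt1, Gbp3, Gm18852, Gstm1, H2-Ab1, Hhip, Hopx, Ier3, Il19, Il24, Inmt, Itgam, Itgax, Jag1, Krt15, Krt2, Krt78, Krt80, Lce1l, Maf, Mal, Nfe2l2, Npy1r, Pmp22, Pnpla2, Ptgs2, Sptlc3, Tgm1, Tgm5, Tyrp1 and Vwf. For lists, 354 of 418 were kept, 59 lost and 5 gained. Without single arrays, the medians of the uncalled lists of epidermal keratins, desmosomes, differentiation regulators, smooth muscle, sweat gland, Schwann cells and cartilage, all within 0.1 of 0, also moved by over 1.5 times or turned their sign. Apart from the 2-fold minimum, the cause was not tested. Signal over background limits dim genes: 22758 of 30666 lay above the Y-linked level in females (3.37).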

Other observations

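All families and genes in this part were chosen for naming after their values were seen. Calls of single genes come from the planned fit over all genes, and some belong to the fixed lists. The family counts and the neighbour test were not planned. Medians of the families kept their sign under both scaling alternatives. All 4 gasdermin C genes rose (median 3.16), with Gsdmc3 up by 3.54, as did all 3 Serpinb3 protease inhibitor genes (median 1.70) and 10 of 12 stefin genes (median 2.19). Only part of the Tmprss11 serine protease genes (4 of 7, median 1.58) and of the kallikrein-related peptidase genes (8 of 12, median 0.68, Klk6 by 3.29) rose, and 0 fell. All 6 Lce3 genes rose (median 3.72) while 11 of 13 Lce1 genes fell (median -0.46), and all 9 Sprr2 genes rose (median 4.11). All 5 chitinase-like genes rose (median 1.48), and all 5 transporter genes of the Abca5 group fell (-1.12 to -0.53). Of 49 keratin-associated protein genes 0 rose and 2 fell (median -0.42). Probe sets of such paralogs can share signal, which was not tested.

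Among single genes, the alarmin gene Il33 rose from 5.89 ± 0.33 to 8.95 ± 0.18 (3.06, adjusted p = 5.36e-06), the defensin gene Defb4 by 3.53, the cytokine gene Il1b by 2.22 and the arginase gene Arg1 by 2.01. The T cell cytokine genes Il17a, Il17f and Il22 differed by -0.03, 0.04 and 0.06, not past the threshold. Their mean signals of at most 3.82 lay under the negative control medians of 4.26 to 4.46, so a change could be missed. The genes Lyve1, Folr2 and F13a1, expressed by resident macrophages of connective tissue, fell by 1.21, 1.20 and 1.21 (adjusted p = 0.0124, 0.0249 and 0.0309). The NRF2 target gene Nqo1 rose by 1.19 and the proliferation gene Mki67 by 0.34.

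The clock genes Dbp and Per3 fell by 0.65 and 0.60, while Arntl, Clock and Npas2 differed by -0.12, 0.10 and -0.37, not past the threshold. Of 58 genes that rose at least 4-fold, 33 lay within 3 genes of another in the RefSeq gene order of GRCm38.p6. In 10000 shuffles the median was 0 and the highest value 8 (permutation p = 1e-04, the smallest they can give). Paralog families such as Sprr2, Lce3 and gasdermin C rose as a whole, and shuffles of single genes do not keep neighbouring paralogs together. The small p is therefore no evidence that the place of a gene matters by itself. Among probe sets without a tested gene, 1886 of 35290 (5.34%) were called when all non-control probe sets were tested together, against 9.64% of those with one.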
